A study of Mus musculus with 8 samples.

How the data were processed

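Samples were grouped by their titles into 4 SUDEP and 4 control mice, described by the labels as biological replicates; all were male and 5 weeks old. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was removed, and labelled cRNA was made along the whole transcript by random priming with the dye Cy3. The labels give the source as brain tissue and the series text as brainstem. The array was the Arraystar mouse lncRNA Microarray V3.0, with 62939 spots and 60915 non-control probes. Arrays were read with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes.

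The scanner files hold, per the file headers, a processed intensity of each spot, which is background-subtracted and spatially detrended, with low values replaced by a surrogate, and not normalized between arrays. They also hold the median intensity of the spot and of its local background. A second, deposited table holds the authors' processed values of the same arrays on a log2 scale. The method behind that table is not given in the sources used here. Each of its columns was checked against the scanner values: it correlated best with its own array (r from 0.995 to 1.00) and ran in the same direction. Quantile normalization of intensities floored at 5 came within a median of 0.02 to 0.03 log2 units of it. The column medians were 6.44 in all 8 arrays. 126 probe names of the scanner files, the 15 reference probes among them, are not in that table, and it was used as an alternative only.

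From the scanner files, spots marked as non-uniform or as population outliers (0.0529% of non-control spot values) were set to missing. Control spots and 15 probes named as negatives were left out, spots of one probe were averaged as log2 processed intensity, and the 75th percentile of each array was subtracted. A value of 0 is therefore the 75th percentile of that array. Probes well above background on at least 4 of the 8 arrays (49297 probes, 80.9%) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with group as the only term, and Benjamini-Hochberg adjustment over all tested probes. Probes with an adjusted p under 0.05 were counted. Where no array of a group was well above background, the fold was given as a bound: the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value among probes well above background. The precision is limited by the number of arrays. Values were simulated for 49191 probes, of which 200 were changed in the SUDEP group. The noise was normal and independent between probes, with the SDs of the real probes shuffled among them. The fit recovered 77 of 100 probes changed 2-fold and 93 of 100 changed 4-fold, with 2 false calls. Structure shared among the arrays was not simulated, so these counts need not hold for the real data. Single values per array were compared with exact permutation tests, whose smallest p here is 0.0286.

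Gene names were taken only from accessions in the scanner files, matched without versions to a RefSeq gene table of assembly GRCm38.p6. All 15 reference probes, each with 20 spots, matched. The other 60900 probes carry identifiers that the files do not pair with genes, so their genes and transcript classes are not used here. For this reason 27 gene lists, fixed before the data were examined, could not be tested: none of their 515 members is among the 15 reference genes, and the gene set tests (camera, fry) were not run. Pgk1, a member of the hypoxia list, was seen only through quality-control spots. The rule for named genes, fixed at the same time, asked for the genes with the largest change past the threshold in each direction whose groups do not overlap. It was applied to the probes with the identifiers kept to 2 per direction, ranked among those measured in both groups, and all 15 reference genes were named because these alone carry a name. The other parts of the rule, on gene lists, noncoding class and 8 fixed genes, could not be applied. The probe numbered 1 below a named probe and the lincRNA-named probe were singled out after their values were seen.

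All 8 arrays share 1 scan time. The array codes in the file headers have a first number that is the same for all control arrays and another that is the same for all SUDEP arrays, so whatever it stands for cannot be told apart from the group, and no slide term could be fitted. Alternatives were quantile, median and cyclic loess scaling, normexp background correction with an offset of 50, other filters on dim probes, the deposited table, other variance models, an unmoderated test, other thresholds, the replicate number as a block, and each array left out in turn. Normexp was run on median intensities, since the mean intensity is not a column of the files. Figures were drawn with matplotlib 3.10.9.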

Results

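RNA from the brainstem of 8 male DBA/1 mice aged 5 weeks was measured on a 1-colour array of mouse long noncoding RNAs and mRNAs. DBA/1 is an inbred strain in which sound-induced seizures can end in respiratory arrest, and it is used to study sudden unexpected death in epilepsy (SUDEP). The 8 arrays came from 4 mice of the SUDEP model and 4 normal mice of the same strain, called control here, with 1 array per mouse. How the model was induced, and when tissue was taken after a seizure, are not given in the sources used here. The 75th percentile of probe intensity was 458 and 455 in control 1 and 2 and between 352 (SUDEP 1) and 377 (SUDEP 2) in the other 6 arrays. Between 74.5% of probes (SUDEP 1) and 83.3% (SUDEP 3) lay well above background, and no spot was saturated. Mean 75th percentiles were 407 ± 57.0 in control and 363 ± 10.99 in SUDEP (SD, n = 4 each), a difference that did not pass a two-sided exact permutation test (p = 0.314). The log2 ratio of the 3′ to the 5′ control spots of Gapdh, a glycolytic enzyme gene, was 1.83 ± 0.17 in control and 1.81 ± 0.08 in SUDEP (SD, n = 4 each, exact permutation p = 0.857). That of Pgk1, also glycolytic, was 7.55 ± 0.19 and 7.51 ± 0.07 (SD, n = 4 each, exact permutation p = 0.714). Over the tested probes, any pair of arrays correlated with a Pearson r between 0.988 and 0.994.

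The comparison addressed which long noncoding RNAs and mRNAs differ between the brainstem of SUDEP mice and that of control mice. The files pair gene accessions with only 15 reference probes, so the results are given for these 15 genes by name and for the other probes by identifier or count. B2m was higher in SUDEP mice. It encodes β2-microglobulin, the light chain of major histocompatibility complex class I molecules. Its normalized log2 intensity was 3.35 ± 0.15 in SUDEP and 2.48 ± 0.16 in control (SD, n = 4 each), with every SUDEP mouse above every control mouse. The log2 difference was 0.88 (SE 0.12, 95% half-width 0.26), or 1.83-fold, with a limma adjusted p of 0.0387 over all tested probes and 2.74e-04 over the 15 reference genes. Of the 20 B2m spots on the array, 18 were measured in all 8 mice, and in each of these 18 the 4 SUDEP mice lay above the 4 control mice, with log2 differences of 0.84 to 0.94 per spot. With 1 array left out the log2 difference stayed between 0.80 and 0.93, but the limma call was lost without control 1, 2, 3 or 4 (adjusted p = 0.136, 0.127, 0.0821 and 0.0744) and without SUDEP 2, 3 or 4 (adjusted p = 0.124, 0.0956 and 0.0931). It was also lost when the array's 75th percentile entered the fit as a covariate (log2 difference 0.77, adjusted p = 0.161), and without the 2 brightest arrays, control 1 and 2, together (0.76, adjusted p = 0.326). With no filter on dim probes its adjusted p was 0.111 and with an unmoderated test 0.403; it passed in 9 of 21 alternatives.

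The other 14 reference genes did not pass the test. Tfrc, the transferrin receptor, had a log2 difference of 0.32 (SE 0.12), with a limma adjusted p of 0.547 over all probes and 0.212 over the reference genes. Nono, which encodes a nuclear RNA-binding protein, had a difference of 0.28 (SE 0.20, adjusted p = 0.779 by limma), and Tuba1b, an alpha-tubulin, of 0.16 (SE 0.12, adjusted p = 0.779). For Actb, encoding beta-actin, the value was 0.07 (SE 0.09), for Gapdh 0.03 (SE 0.11), for Hprt, a purine salvage enzyme, 0.08 (SE 0.11) and for Tbp, the TATA-binding protein, 0.06 (SE 0.09). The cyclophilin gene Ppia had 0.02 (SE 0.12), the heat shock protein gene Hsp90ab1 -0.02 (SE 0.11) and the ribosomal protein gene Rpl13a 0.01 (SE 0.12). Gusb, a lysosomal enzyme, had 0.15 (SE 0.12), Gk, glycerol kinase, -0.13 (SE 0.12), G6pd2, a glucose-6-phosphate dehydrogenase, 0.10 (SE 0.10) and Ldhal6b, a lactate dehydrogenase-like gene, -0.08 (SE 0.12). Across the 5 scalings and background corrections tried, these 14 genes lay between -0.14 and 0.35 and none passed, while B2m lay between 0.82 and 0.90. The sign turned for Hsp90ab1 with quantile scaling (0.02) and for Ppia (-0.02) and Ldhal6b (0.02) with normexp on the median intensity.

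**Figure D1:**
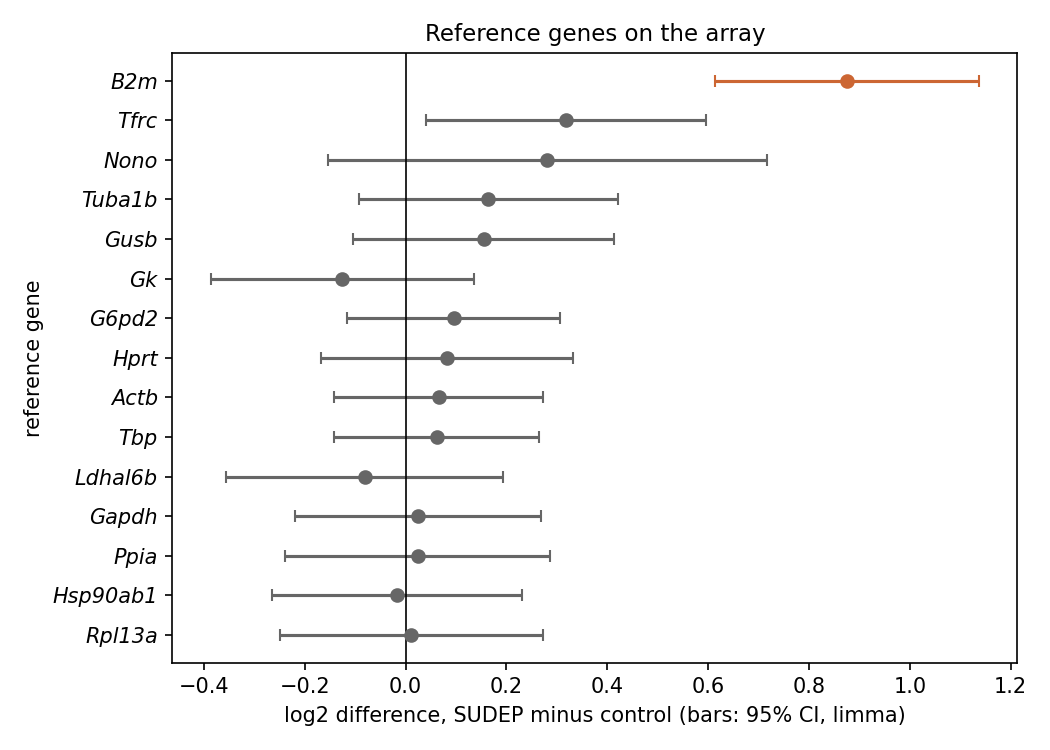
Log2 difference in intensity, SUDEP minus control (x axis), for the 15 reference genes (y axis), from limma on 4 arrays per group. Points are estimates and bars 95% confidence intervals. B2m (orange), at 0.88, is the 1 gene past the adjusted threshold; the next, Tfrc, is at 0.32.

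Among the 49297 probes tested, 32 differed between SUDEP and control mice at a limma adjusted p under 0.05. Of these, 18 were higher in SUDEP and 14 lower, and 24 differed by at least 2-fold (13 higher, 11 lower). With normexp background correction of the median intensity, in place of the processed intensity, 240 probes passed, 69 higher and 171 lower. An unmoderated test called 0 (3723 at an unadjusted p under 0.05). In all 32 the 4 SUDEP values lay beyond the 4 control values, which largely follows from choosing them by p in the same arrays. Over all tested probes 2356 did so, or 4.78% where chance gives 2.86%. Probes are not independent, and this share was not compared with other splits of the arrays, so chance is not excluded for it. The rise with the largest log2 difference among called probes measured in both groups was that of probe ASMM10P018237. Its normalized log2 intensity was 6.74 ± 0.58 in SUDEP and 2.56 ± 0.84 in control (SD, n = 4 each), a difference of 4.18 (SE 0.40, 18.1-fold, limma adjusted p = 0.00908). Probe ASMM10P014816 rose by 2.77 (SE 0.31, 6.84-fold, adjusted p = 0.0190), from -4.09 ± 0.13 to -1.32 ± 0.78. Probe ASMM10P016002 fell by 3.24 on the log2 scale (SE 0.23, 9.47-fold, adjusted p = 0.00166), from 2.12 ± 0.53 in control to -1.12 ± 0.16 in SUDEP. The probe numbered 1 lower fell as well, from 2.75 ± 0.46 to 1.08 ± 0.19 (log2 difference -1.68, adjusted p = 0.0278). Probe ASMM10UP778 fell by 1.90 (SE 0.23, 3.74-fold, adjusted p = 0.0278), from -3.08 ± 0.56 to -4.99 ± 0.14. It was well above background in 2 of the 4 SUDEP mice. Being above background does not by itself show a transcript: 2 probes named as negatives were also well above background on all 8 arrays. Their intensities were 21.4 to 46.3 and 33.7 to 48.0. The SUDEP values of ASMM10UP778 and the control values of ASMM10P014816 lay within or below these intensities. Their folds are therefore measured against a level that negatives also reached. Of the 32 called probes, 21 were well above background on all 8 arrays. Some of these 21 were as dim: the control mean was -4.17 in 1 and -4.31 in another, below that of ASMM10P014816 (-4.09). The limit set by the negatives thus applies to more of the 32 than the 2 probes named, and how many was not counted. In 2 of the 32 no control mouse was well above background, so their rise is a bound. It was at least 4.93-fold (limma adjusted p = 0.0440) in 1 and at least 1.72-fold (adjusted p = 0.0446) in the other. In the latter even the SUDEP values (mean -4.13) lay within or below the intensities of the 2 negatives.

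**Figure D2:**
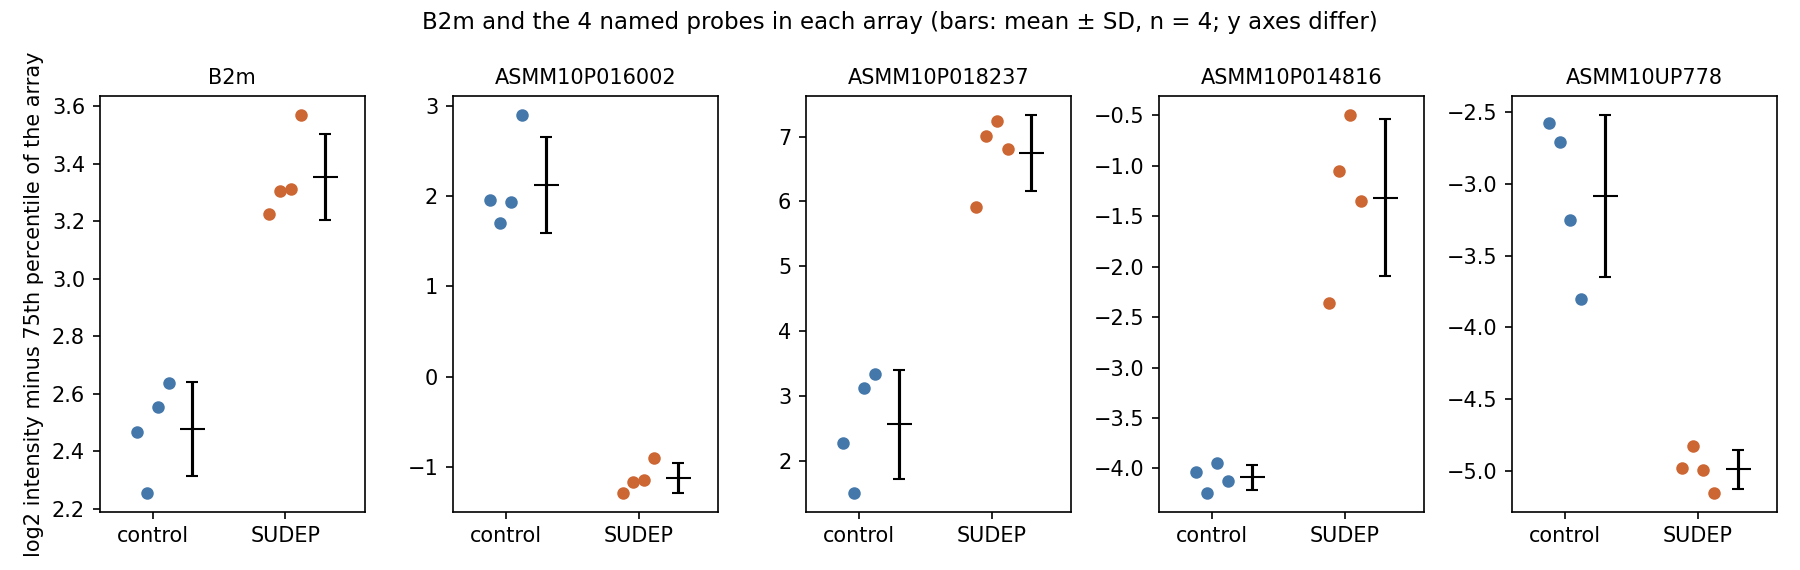
Normalized log2 intensity (y axis, own scale per panel; 0 is the array's 75th percentile) of B2m and of the 4 probes named in the text, in control (blue) and SUDEP (orange) mice. Each point is 1 mouse, and bars show the mean ± SD (n = 4). In each panel the groups do not overlap; for ASMM10P018237 the means are 2.56 in control and 6.74 in SUDEP.

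Leaving out single arrays changed how many probes passed. Without control 1, 2, 3 or 4 the count was 5, 6, 12 and 13, and without SUDEP 1, 2, 3 or 4 it was 62, 12, 9 and 10; without control 1 and 2 together it was 2. ASMM10P016002 passed in each of these 8 fits, and ASMM10P018237 in all but the fit without control 1 (adjusted p = 0.0690). Without control 1 and 2 together ASMM10P016002 passed (adjusted p = 0.0318), and ASMM10P018237 did not (log2 difference 3.51, adjusted p = 0.0940). Nor did ASMM10P014816 (2.72, limma adjusted p = 0.331) or ASMM10UP778 (-1.46, adjusted p = 0.151). Of the 8 fits with 1 array left out, ASMM10P014816 passed only without SUDEP 1 or SUDEP 3, with an adjusted p of 0.0511 (without SUDEP 4) to 0.112 (without control 2) in the other 6. ASMM10UP778 passed only without control 4 or SUDEP 1, with 0.0674 (without control 3) to 0.127 (without control 2) in the other 6. These 2 dim probes had smaller log2 differences, of 1.39 and -0.51, with normexp on the median intensity. That setting changes the signal and its background correction and adds an offset of 50. Both probes passed there.

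**Figure D3:**
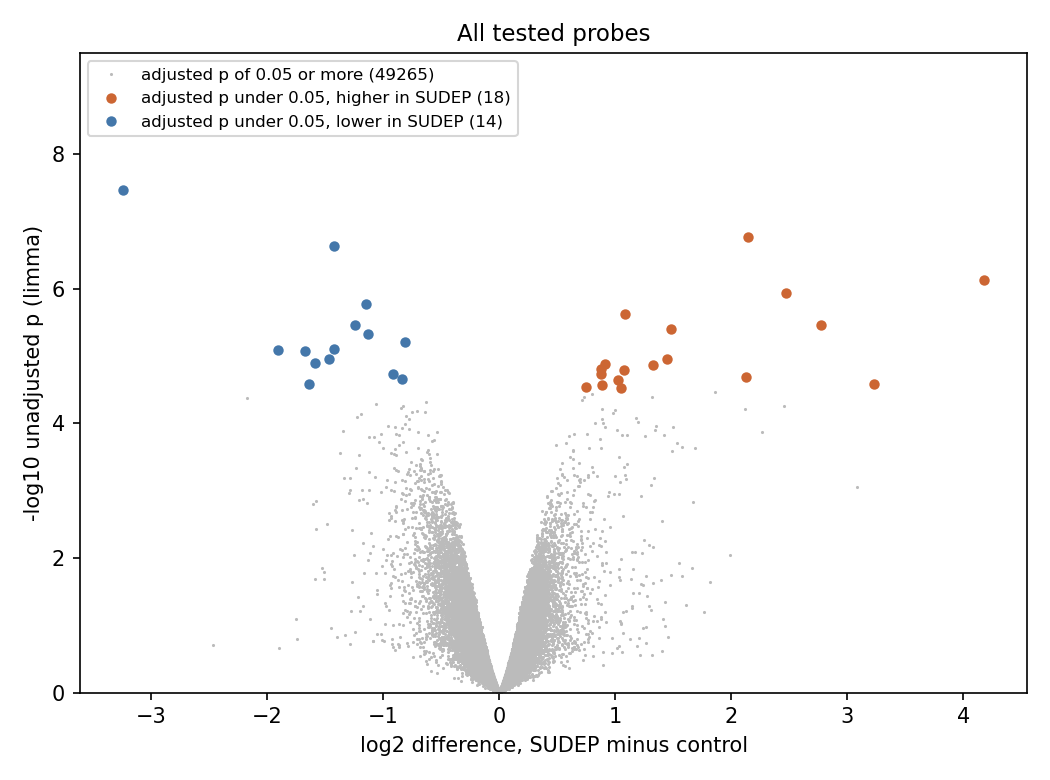
Log2 difference, SUDEP minus control (x axis), against -log10 of the unadjusted limma p (y axis) for the 49297 tested probes. Orange marks the 18 probes higher and blue the 14 lower in SUDEP at an adjusted p under 0.05, from -3.24 to 4.18 on the x axis.

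Most probes differed little. The middle 50% of log2 differences lay between -0.10 and 0.11. At an unadjusted limma p under 0.05 there were 4006 probes, 8.13% of those tested, where 2465 are expected by chance; 1696 were higher in SUDEP and 2310 lower. As many probes or more came from 5 of the 35 ways to split the 8 arrays into 4 and 4, up to 6695. Requiring also a 2-fold difference left 132 probes, 74 higher and 58 lower. Of these 132, 61 (46.2%) were well above background on all 8 arrays, against 90.3% of all tested probes.

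The design text asks for long noncoding RNAs as well as mRNAs. Here only probes whose names hold the word lincRNA, for long intergenic noncoding RNA, can be set apart, and the class of the other probes is not used here. Of 1836 such probes 1096 were tested: 644 with humanlincRNA names, 397 with mouselincRNA names and 55 with MM9LINCRNAEXON names. The 1 probe that passed the limma adjusted threshold had a humanlincRNA name. It was lower in SUDEP, at -4.76 ± 0.43 against -3.12 ± 0.37 in control (log2 difference -1.64, adjusted p = 0.0440). Its SUDEP values lay below the intensities of the 2 negatives that were well above background on all 8 arrays. In 12 of the alternatives no lincRNA-named probe passed. At an unadjusted p under 0.05 there were 117 lincRNA-named probes, 39 higher and 78 lower. That is 10.7% of those tested against 8.07% of the other probes (odds ratio 1.36, two-sided Fisher's exact p = 0.00250, adjusted over 3 such tests 0.00751), but probes are not independent, and 5 of the 35 ways to split the 8 arrays into 4 and 4 gave an odds ratio as large, up to 1.56. Among the 569 tested probes of another name family, ASMM10UP, the share was 10.9%. Past 2-fold as well there were 3 lincRNA-named probes, each with a humanlincRNA name and lower in SUDEP.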

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

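In 2 of the 46 groups of 4 arrays examined (the 15 reference genes, the 4 named probes and 4 measures of array quality, in each group), 1 mouse stood far from the other 3; chance gives about 1 in 20, or 2.3. Tuba1b, an alpha-tubulin gene, was at a normalized log2 intensity of 7.03 in SUDEP 2 and between 7.20 and 7.23 in the other 3 SUDEP mice, so that its gap to the nearest was 0.853 of the range. Ppia, encoding cyclophilin A, was at 6.85 in SUDEP 1 and between 6.66 and 6.68 in the other 3, a gap of 0.918 of the range. No explanation was tested for either. Among 47 control features outside the tested probes that were above background, none differed between the groups by limma (0 at an adjusted p under 0.05 and 0 at an unadjusted p under 0.05).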

How the results depend on the processing

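The alternatives were planned before the data were examined, except normexp on median intensities, the 75th percentile as a covariate, control 1 and 2 left out together, and the block of array codes. Against 32 probes past the adjusted threshold, the count was 50 with median scaling, 57 with probes above background on all 8 arrays, 73 with trended and robust variance, 21 with array weights, 6 with no filter, 58 with array codes 1 and 2 against 3 and 4 as a block, 8 with the covariate, 2 without control 1 and 2, and 132 at unadjusted p and 2-fold. An unmoderated test called 0 (3723 at an unadjusted p under 0.05). Normexp called 240, of which 28.75% were higher in SUDEP against 56.25% in the 32 (69 higher, 171 lower). Quantile scaling, cyclic loess and the deposited table gave 46, 47 and 46. Leaving out 1 array gave 5 (without control 1) to 62 (without SUDEP 1), of which 5 to 28 were among the 32. The cause of these changes was not tested.

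With the replicate number as a block 13 probes passed, 11 of them among the 32, and B2m and ASMM10P014816 did not (adjusted p = 0.0875 and 0.0647). The deviations of same-numbered mice correlated for numbers 2 and 4 (r = 0.30 and 0.16), each the best match of the other, and not for 1 and 3 (r = -0.07 and 0.00), so the numbers were not taken to pair the mice; 4 of the 8 arrays correlated best with their own number.

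The 1 lincRNA-named probe became 2 with quantile scaling, cyclic loess or the deposited table, 8 with normexp and 3 at unadjusted p and 2-fold. It became 0 by limma with probes above background on all 8 arrays, no filter, array weights, the replicate block, the covariate or without control 1 and 2, and 0 by the unmoderated test; leaving out 1 array gave 0 to 1. In these fits with 0, 85 to 148 passed an unadjusted p under 0.05.

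B2m and the 4 probes named by identifier changed direction in none of the alternatives run. For most alternatives this was fixed in advance. The groups do not overlap in these probes, so leaving out or weighting arrays cannot turn the sign. Other filters, variance models, the unmoderated test and the blocks keep the same estimate. Only the scalings, the background correction, the deposited table and the covariate could have turned it. B2m stayed past the threshold in 9 of 21 alternatives (log2 0.76 to 0.93, adjusted p 0.00537 to 0.403), ASMM10P016002 in 21 of 22, ASMM10P018237 in 18 of 22, ASMM10P014816 in 11 of 22 and ASMM10UP778 in 12 of 21. Gene list tests were not run, for want of gene names. A slide term was not run, since the first array code number differs between the groups and what it stands for is not given. Of the 132 probes, 46.2% were above background on all 8 arrays, against 90.3% of all tested probes. How dimness affects precision was not tested.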

Other observations

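The split test of all probes at an unadjusted p, the test of B2m against array scaling and the count of runs of consecutive probes were chosen after the result was seen. Single mice differed in how many probes stood 2-fold beyond all other 7 mice. SUDEP 1 had 96 probes above and 67 below all others, and SUDEP 3 had 85 above and 40 below. The other 6 mice had 20 (control 2) to 36 (control 4) above and 6 (control 3) to 30 (control 4) below. SUDEP 1 was also the array with the lowest share of probes above background, 74.5%, and SUDEP 3 the one with the highest, 83.3%. No explanation was tested for this. Of the 15 probes named as negatives, 2 were well above background on all 8 arrays, at mean intensities of 21.4 to 46.3 and 33.7 to 48.0.

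The labelled grouping was compared with all 35 splits of the 8 arrays into 4 and 4. Only the labelled one (1 of 35) gave as many as 32 probes past the adjusted threshold, and any other gave 0. Chance could be excluded for that count only if the 8 arrays were alike, and the split by code numbers described below goes against that. With the same limit, only the labelled split gave as many as the 132 probes at unadjusted p and 2-fold (1 of 35, the highest other 67). For the 1 lincRNA-named probe past the adjusted threshold the splits decide nothing, since the others called 0 probes of any kind. Chance could not be excluded for the 4006 probes at unadjusted p alone: 5 of the 35 splits gave as many, up to 6695. For the 117 lincRNA-named probes at unadjusted p, 3 of the 35 splits gave as many, up to 132. The odds ratio of these against other probes was 1.36. Of the 35 splits, 5 gave one as large, the labelled one included, up to 1.56. Chance could therefore not be excluded for the excess of lincRNA-named probes.

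The split with 6695 probes set the arrays with code numbers 1 and 2 against those with 3 and 4, with 2 mice of each group on either side. This points to a structure among the arrays that is not the group. Only 18 of the 35 splits keep 2 arrays of either set on each side, too few for a share under 0.05; among them the labelled one gave 32 probes past the adjusted threshold and the highest other 0, and 4006 at unadjusted p against 3063. With these 2 sets of arrays as a block, a choice made because this split had the highest count, 58 probes passed the adjusted threshold, 31 of them among the 32, and B2m had an adjusted p of 0.0214, where its range over all alternatives was 0.00537 to 0.403. With each of the 4 code numbers, which are also the replicate numbers, as a block, 13 probes passed, 11 of them among the 32, and B2m did not (adjusted p = 0.0875).

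B2m, the 1 reference gene that differed, was 0.88 higher in SUDEP on the log2 scale. The values argue against array scaling, since the median log2 difference of the other 14 reference genes was 0.0637 (SD 0.12), while the lower 95% bound for B2m was 0.61. A local fault of the array surface is also argued against, since all 18 B2m spots measured in all 8 mice (of 20, spread over the array) had every SUDEP mouse above every control mouse; the other 2 spots lacked values in 1 or more SUDEP mice. The array position or slide code stays open: 0 of the first code numbers hold both groups, so it cannot be told apart from the SUDEP model. That the model itself raises B2m, a gene that interferon induces, therefore may hold but was not tested apart from this.

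The 2 probes of consecutive number that fell together (-3.24 and -1.68) do not lie side by side on the array: their spots are 137 rows and 111 columns apart, so a local fault does not account for the pair. A candidate explanation is that probes of consecutive number often measure related transcripts. Their deviations from the group means had a mean correlation of 0.0385 over probe pairs, above the central 95% of 1000 shuffles of the numbers (0.00389 to 0.0125), and it was 0.0119 for numbers 1000 apart. The pairs past an unadjusted p in the same direction (146, shuffles 109 to 153) and the runs of 3 or more (8, shuffles 1 to 9) were not beyond chance. By the rule set before the result was seen, the pair count goes against this explanation, while the correlation goes with it. Unrelated pairs dilute the counts, so the counts cannot exclude it, while dilution cannot raise the mean correlation. The highest of the shuffles was 0.0147, and numbers 2 apart had 0.0288. Probes of consecutive number thus co-varied weakly, beyond the shuffles. Whether they do so because they measure related transcripts was not tested. Whether these 2 probes share a gene was not tested, since their genes are not used here.

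The longest such run held 6 probes of consecutive number, all higher in SUDEP, with log2 differences of 0.34 to 0.91 and unadjusted limma p from 1.33e-05 to 0.00925; 1 of the 6 passed the adjusted threshold. None of the 1000 shuffles had a run as long, the longest being 5.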
